A study of Arabidopsis thaliana with 12 samples.

How the data were processed

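The data are 12 expression arrays of whole Arabidopsis thaliana seedlings, 3 days old, in 4 groups of 3: wild type (WT, Col-0) or an estradiol-inducible tor RNAi line (tor), each kept without glucose (none) or given 15 mM glucose for 2 h. Groups and replicate numbers were taken from the labels, which call the replicates biological. Whether the WT seedlings also received estradiol is not given in the sources used here, so an effect of the inducer and one of the silencing are not separated in comparisons of the genotypes. Total RNA was labelled with biotin by the authors.

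Per the submitters' processing notes, the authors summarised the arrays with RMA (version not given), and the deposited values per probe set are on the log2 scale. Whether both genotypes were normalized together is not given in the sources used here. The authors also deposited a comparison of glucose with none for each genotype, and per the file headers each holds log2 fold changes from dChip and from RMA, rounded to 1 decimal, and a p-value for each. The test behind the authors' p-value and any adjustment are not stated. The deposited RMA fold change lay within 0.05 of the difference of the group means for all 22746 probe sets compared in WT and all 22745 in tor. With p under 0.05 the deposited tables hold 7893 probe sets by RMA and 8033 by dChip for WT, and 366 and 395 for tor. After Benjamini-Hochberg adjustment of the deposited p-values, 5909 and 5717 remain for WT, and 0 and 0 for tor. The report's values come from the fits described next, not from these tables.

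Of 22810 probe sets, 64 controls were left out and 22746 were tested. Of these, 13513 carry 1 gene in the sources used here, 503 carry several and are not named, and 8730 carry no gene name here and enter counts only, so a gene missing from the text was not necessarily missing from the array. The named probe sets cover 13286 genes, 144 of them with more than 1 probe set; among the 34 of these with a call in WT, 23 were called by some but not all of their probe sets and 1 in both directions. TOR has no named probe set here, so its silencing was not checked on these arrays.

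All 12 arrays entered one linear model per probe set with a mean per group (limma 3.58.1 in R 4.3.3, lmFit and eBayes). From it 5 comparisons were drawn: glucose against none in WT and in tor, the difference of these responses (tor minus WT, the interaction), and tor against WT without and with glucose. P-values are two-sided and were adjusted by Benjamini-Hochberg over all tested probe sets within a comparison, and a probe set was called at an adjusted p under 0.05. Errors of single genes are standard errors of the model, those of list medians are the SD over the 3 differences between arrays of the same number. No replicate block was used. Afterwards, replicate numbers were checked for pairing: after removal of group means, the 18 pairs of same-numbered arrays correlated at 0.199 to 0.863. For 12 of 12 arrays, the mean correlation with the arrays of the other groups was highest for their own number. A block on the number was therefore given weight as an alternative and the list members whose calls change with it are counted with each comparison.

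The comparisons, tests, alternatives, 20 gene lists and the rule for naming genes were fixed before the data were examined. By that rule each comparison names genes among the 8 highest and 8 lowest log2 changes of called probe sets with 1 gene and no overlap between the arrays of the groups, up to 4 called members of each list with the largest change, or, where none passes, the member with the smallest p. Genes outside the rule are said to have been chosen later. For each list the members measured, called over all probe sets and called after adjustment over the list alone were counted. Lists with at least 5 members measured (4 of the 20: cytosolic ribosomal proteins, ribosome biogenesis, sugar starvation and autophagy) were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation and with fry. Camera asks whether a list moves more than the other genes, fry whether its genes move one way on balance. The fry tests and those with an estimated correlation were run without a block on the replicate number. They leave out the pairing of same-numbered arrays. The other 16, which cover the TOR pathway, S phase, mitosis, beta-oxidation and the glyoxylate cycle, glycolysis and the TCA cycle, nitrogen assimilation, photosynthesis, flavonoids, glucosinolates, cell wall, root meristem, root hairs, seed storage, handling stress, the clock and reference genes, were only counted. Nitrogen assimilation and seed storage had 0 members measured. A member counts as measured only if a probe set carries its gene name here. The lists tested hold more genes than those measured, and the others may lie among the probe sets without a name. A further 4 lists (a wider one of ribosomal proteins, a wider one of ribosome biogenesis, cytosolic chaperonin and small heat-shock proteins) were written after the data were seen and are given under the other observations.

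The alternatives were a block on the replicate number, a second quantile normalization, centring of each array on its median, leaving out the dimmest 40% of probe sets, fits of only the arrays compared, eBayes with trend and robust settings, array weights, probe sets of a gene averaged for lists, and leaving out each array in turn. Added after the data were seen were a block within each genotype, a block in fits of only the arrays compared, and leaving out the 4 arrays numbered 1.

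Precision is set by the 3 arrays per group and by signal over background. It was tested on simulated data drawn with the mean and residual SD of each probe set, with known changes added. The draws were independent between probe sets and between arrays, so they lack the correlation of same-numbered arrays. For glucose in WT, 75.0% of 100 probe sets changed by a log2 of 1 and 88.0% of 100 changed by 2 were called, with 10 false calls, and in tor 58.0% and 86.0%, with 4 false calls. The same mean and SD served all groups, so these WT and tor figures differ only by the random draw. They do not show a lower precision in tor. When 4549 probe sets were changed by 1 in tor, 85.1% were called. Changes smaller than 1 were not simulated, so these figures do not show how many of those would be called.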

Results

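Glucose at 15 mM for 2 h changed a large part of the transcriptome of wild-type (WT) seedlings that had used up their seed reserves over 3 days in low light. Of the listed genes with a named probe set here, which are a part of each list, 6 of 7 of ribosome biogenesis and both of DNA replication rose. In contrast, 5 of 5 sugar starvation genes, 3 of them of leucine breakdown (MCCA, MCCB and IVD), and 8 of 14 autophagy genes fell. In seedlings carrying the estradiol-inducible RNAi construct against tor (tor seedlings), no single probe set passed for the same treatment, and 1220 probe sets changed differently in the 2 genotypes. Both counts come from a fit that leaves out the pairing of same-numbered arrays. With the replicate number as a block they were 0 and 3043, and the tor arrays alone with the block gave 20. The p-values measure the spread between these arrays, 3 per group, which the labels describe as biological replicates. TOR itself has no probe set with a gene name in the sources used here and was not analysed here.

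In WT seedlings 3077 probe sets rose with glucose and 2377 fell, 24.0% of the 22746 tested. Among them 1273 rose and 1000 fell by at least 2-fold. The ribosome assembly gene AT3G15460 (BRX1-1) rose from a log2 level of 5.29 to 8.86, a log2 change of 3.57 ± 0.19 (SE, adjusted p = 9.27e-06). ICU2, the catalytic subunit of DNA polymerase alpha, rose by 2.42 ± 0.30 (adjusted p = 0.000336), and PRL, the MCM7 subunit of the replicative helicase, by 2.41 ± 0.47 (adjusted p = 0.00411). Among probe sets that carry 1 gene name here, which 8730 lack, the largest rises were of the cytosolic small heat-shock protein genes AT1G53540 (4.48 ± 0.48, adjusted p = 0.000181) and AT2G29500 (4.38 ± 0.32, adjusted p = 3.36e-05), and the flavonol rhamnosyltransferase gene AT1G06000 rose by 3.84 ± 0.49 (adjusted p = 0.000398). MCCA, a subunit of methylcrotonyl-CoA carboxylase in leucine breakdown, fell from 12.03 to 6.66 (-5.36 ± 0.77, adjusted p = 0.000744). GAT1_2.1, a glutamine amidotransferase-like gene, fell by 5.16 ± 0.70 (adjusted p = 0.000552) and PPDK, pyruvate orthophosphate dikinase, by 4.81 ± 0.65 (adjusted p = 0.000552). The rule for naming the highest and lowest genes requires all 3 arrays with glucose to lie on one side of the 3 without, so this is no added support for them. AT1G53540 without glucose (4.01) and AT3G62950 with it (3.86) lay at the level of dark probe sets, below 5. The size of such changes is a lower limit. Rises made up 56.4% of the calls, and 45.6% after the arrays were centred on their medians. The centring took off a shift of 0.09, while the median change over probe sets was -0.01. With the replicate number blocked within each genotype, an alternative chosen after the data were seen, 8903 probe sets passed.

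**Figure D1:**
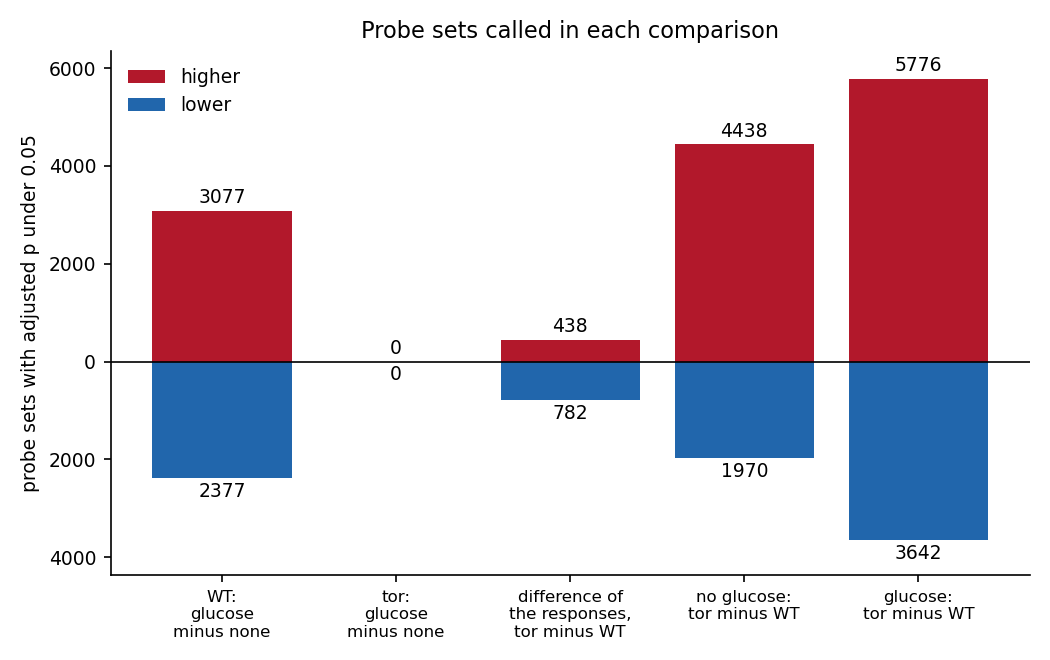
Number of probe sets with adjusted p under 0.05 (limma) in each of the 5 comparisons, those higher and those lower drawn apart, 22746 tested. Glucose in tor seedlings gives 0 calls, glucose in WT seedlings 5454.

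Of 7 ribosome biogenesis genes measured in WT, 6 rose and 1 did not pass (7 rose when adjusted over the list alone), with a median log2 change of 1.76 ± 0.08 (SD over the 3 same-number pairs). NRPA1, the largest subunit of RNA polymerase I, rose by 2.03 ± 0.19 (adjusted p = 0.000102), AT1G52930 (BRX1-2) by 1.81 ± 0.16 (adjusted p = 6.31e-05) and AT3G05060 (NOP58-2) by 1.76 ± 0.19 (adjusted p = 0.000156). Against the other genes the list shifted upward (camera, adjusted p = 1.7e-07) and kept its call with an estimated correlation (adjusted p = 0.0411, alternatives 9.05e-09 to 0.0411). Of 9 cytosolic ribosomal protein genes, 6 rose and 3 did not pass (7 rose when adjusted over the list alone), median 0.57 ± 0.06. AT5G02870 (RPL4D) rose by 1.22 ± 0.22 (adjusted p = 0.00243) and AT3G09630 (RPL4A) by 0.67 ± 0.13 (adjusted p = 0.00353). With the replicate number as a block, 7 of the 7 biogenesis and 7 of the 9 ribosomal protein genes passed. The camera test gave an adjusted p of 0.000386 for the ribosomal protein list, but adjusted p = 0.226 with an estimated correlation (alternatives 7.94e-05 to 0.226).

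Starvation and autophagy genes fell in WT. All 5 sugar starvation genes measured fell, also when adjusted over the list alone, with a median of -3.38 ± 0.93. Besides MCCA, IVD (isovaleryl-CoA dehydrogenase) fell by 3.62 ± 0.68 (adjusted p = 0.0031), MCCB, the partner subunit of MCCA, fell by 3.38 ± 0.48 (adjusted p = 0.000709) and AKINBETA1, a beta subunit of the SnRK1 kinase, fell by 3.26 ± 0.34 (adjusted p = 0.000149). Of 14 autophagy genes, 8 fell and 6 did not pass (13 fell when adjusted over the list alone, 11 with the replicate number as a block), median -0.80 ± 0.32; ATG8E fell by 2.80 ± 0.36 (adjusted p = 0.000424) and ATG8F by 2.08 ± 0.26 (adjusted p = 0.000364). The camera tests gave adjusted p-values of 3.35e-06 for starvation and 2.39e-07 for autophagy. Both calls were lost at adjusted p = 0.0966 with an estimated correlation (alternatives 4.54e-07 to 0.0966 for starvation, 4.12e-08 to 0.0966 for autophagy).

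Lists with fewer than 5 measured members were counted but not tested as lists. In WT both S-phase genes rose, also when adjusted over the list alone. Of 3 genes of beta-oxidation and the glyoxylate cycle, 2 fell and 1 did not pass (2 fell when adjusted over the list alone): the oil-body lipase SDP1 by 1.92 ± 0.35 (adjusted p = 0.00288) and isocitrate lyase, ICL, by 1.68 ± 0.24 (adjusted p = 0.000666). SDH1-1, the flavoprotein of succinate dehydrogenase, rose by 1.12 ± 0.11 (adjusted p = 0.00014), and of the 3 glycolysis and TCA cycle genes it alone passed, over all probe sets and when adjusted over the list alone. UGT74B1, a glucosyltransferase of glucosinolate synthesis, rose by 1.22 ± 0.16 (adjusted p = 0.000548), 1 of 2 glucosinolate genes (2 of 2 when adjusted over the list alone). Of 2 root hair markers, EXPA18 rose (0.85 ± 0.25, adjusted p = 0.033, 1 also when adjusted over the list alone), a call lost without WT_none array 2 (0.127), WT_none array 3 (0.119), WT_glucose array 1 (0.0893), array 2 (0.0545) or array 3 (0.0977). No member passed among 3 mitotic, 2 TOR pathway, 2 photosynthesis, 1 flavonoid, 1 root meristem and 1 clock gene (0 in each when adjusted over the list alone). The same held over all probe sets for 1 cell wall gene, EXPA8, 1 handling stress gene, STZ, and 2 reference genes, each of these lists with 1 call when adjusted over the list alone. A block on the replicate number gave further calls: EXPA8 rose (adjusted p = 0.026), the reference gene PEX4 fell (adjusted p = 0.0211), and 2 of 3 glycolysis and TCA cycle genes rose.

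**Figure D2:**
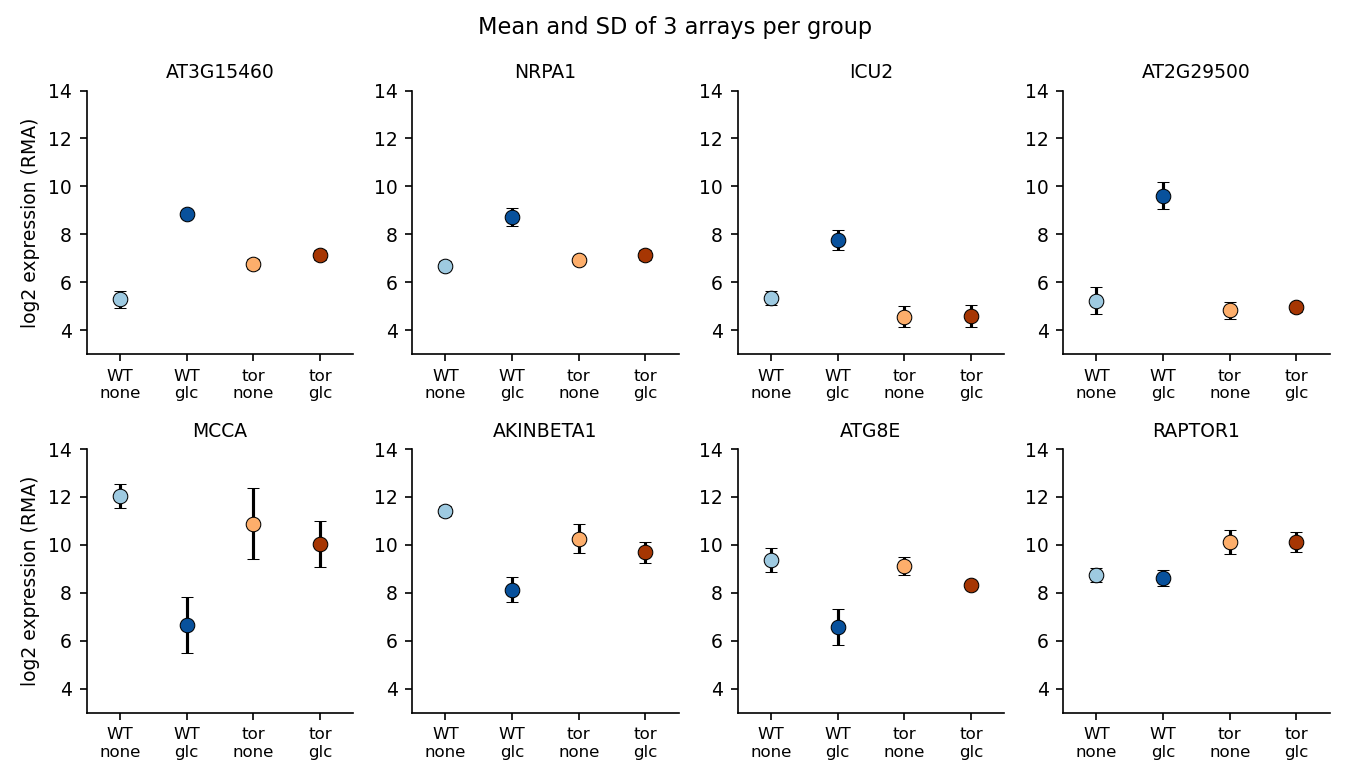
RMA log2 signal of 8 named genes in the 4 groups (glc, with glucose), points for the means and bars for the SD of 3 arrays. AT3G15460 goes from 5.29 to 8.86 with glucose in WT and from 6.78 to 7.14 in tor.

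In tor seedlings 0 probe sets passed (limma), and 313 had an unadjusted p under 0.05. This fit leaves out the pairing of same-number tor arrays, whose deviations correlate at 0.863, 0.678 and 0.811. The 1137 expected by chance do not apply to it. With the block the number was 732, with the block within genotype 1325 and with the tor arrays alone and the block 2478, the last 2 fits chosen after the data were seen. AT3G15460 changed by 0.37 ± 0.19 (adjusted p = 1), ICU2 by 0.04 ± 0.30 and AT2G29500 by 0.13 ± 0.32. In untreated tor ICU2 (4.56) and AT2G29500 (4.83) lay at the level of dark probe sets. Small changes cannot be seen there. The starvation gene MCCB changed by -0.87 ± 0.48 (adjusted p = 1) and ATG8E by -0.81 ± 0.36 (adjusted p = 1), neither past the threshold. The count was 0 in each fit that left out 1 array, 2 probe sets passed without the 4 arrays numbered 1, and 20 in a fit of the 6 tor arrays with the replicate number as a block, both chosen after the data were seen. Lists of genes give a finer measure. The starvation list shifted downward with a median of -0.77 ± 0.49 (camera, adjusted p = 0.000737), the autophagy list with -0.15 ± 0.19 (adjusted p = 0.000737), and the biogenesis list upward with 0.08 ± 0.12 (adjusted p = 0.0406), and 0 of their 5, 14 and 7 members passed (0 also when adjusted over the list alone). With an estimated correlation each of these 3 calls was lost (adjusted p = 0.299). The starvation call was also lost without tor_none array 3 (0.139) or tor_glucose array 1 (0.0693), and the autophagy call without these arrays (0.139 and 0.0693) or tor_none array 2 (0.103). For biogenesis the adjusted p was 0.0543, 0.134 and 0.139 without tor_none array 1, 2 and 3, and 0.109 and 0.162 without tor_glucose array 1 and 3. The lowest alternatives were 1.41e-08 for starvation, 3.5e-07 for autophagy and 0.0248 for biogenesis, and the highest camera value was that with an estimated correlation. The fry test asks whether the genes of a list move one way, not whether they move more than other genes. It gave an adjusted p of 0.487 for all 3. Neither fry nor the estimated correlation took account of the pairing of same-number tor arrays. The 9 ribosomal protein genes had a median of 0.06 ± 0.06 (camera, adjusted p = 0.179), with 0 calls over all probe sets or adjusted over the list alone; leaving out tor_none array 1 (0.000144), tor_glucose array 2 (0.034) or array 3 (0.00302) brought the list past the threshold (alternatives 0.000144 to 0.975).

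The probe sets that responded in WT changed by 13.2% and 13.6% as much in tor. Over the 3077 that rose in WT, the median log2 change was 0.88 ± 0.15 (SD over pairs) in WT and 0.12 ± 0.04 in tor, and 83.6% had the same sign in tor. Over the 2377 that fell, the medians were -0.89 ± 0.29 and -0.12 ± 0.08, with 82.2% of the same sign. By same-number pair the tor medians were 0.08, 0.11 and 0.16 for rising and -0.04, -0.17 and -0.17 for falling probe sets. Their size moved when 1 array was left out. Over the rising probe sets it was 0.05 without tor_glucose array 1, 0.07 without tor_none array 3 and 0.20 without tor_none array 1. Over the falling ones it was -0.21 without tor_none array 1. Leaving out 1 array breaks its same-number pair, so a deviation shared by that pair no longer cancels. Taken from a replicate number not used for the calls, the medians were 1.15 ± 0.43 in WT and 0.14 ± 0.06 in tor for rising probe sets, and -1.30 ± 0.73 and -0.19 ± 0.15 for falling ones. These come from other sets, called from 2 numbers only (523 to 3724 rising and 264 to 3244 falling probe sets). They were not smaller in size than the medians over all arrays. Across the 22746 probe sets, which are not independent replicates, the slope of the tor change on the WT change was 0.154 (Pearson's r = 0.580, Spearman's rho = 0.465).

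**Figure D3:**
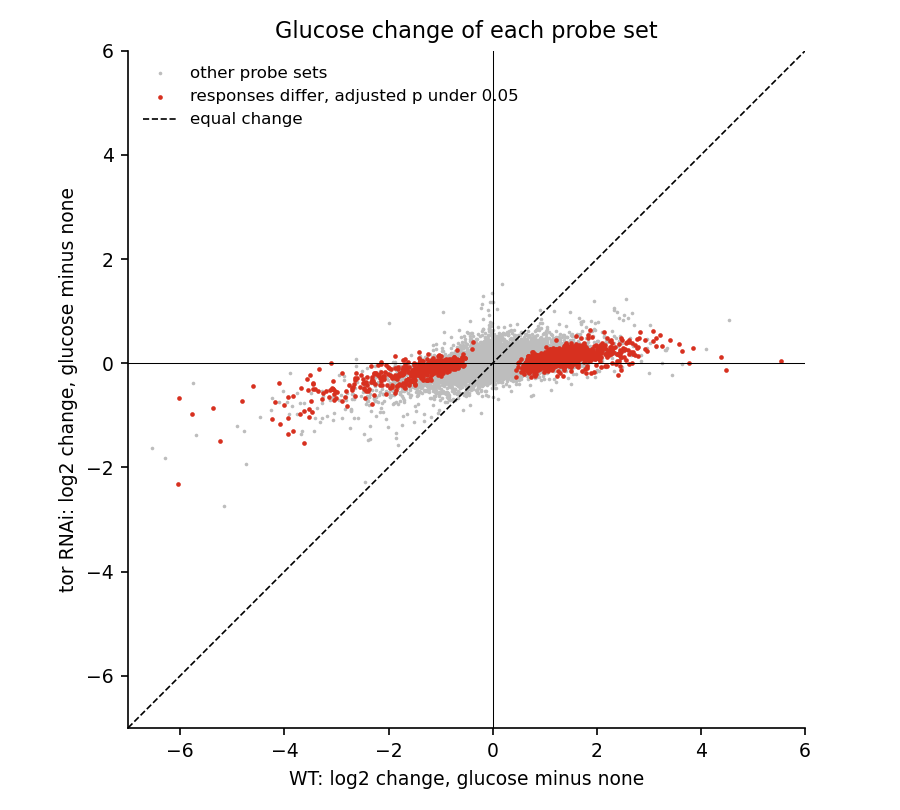
Log2 change with glucose in tor (vertical axis) against WT (horizontal axis) for each probe set, in red the 1220 whose response differed between the genotypes, with a dashed line of equal change. Over the 22746 probe sets the slope is 0.154.

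The glucose response differed between the genotypes for 1220 probe sets, 438 with a higher log2 change in tor and 782 with a lower one. Most of the named genes with the largest differences were WT responders with a small change in tor. The differences of AT1G53540, AT2G29500, ICU2 and AT3G62950 rest on levels below 5 and are not exact sizes. Among them were the small heat-shock protein genes AT1G53540 (-4.60 ± 0.68, adjusted p = 0.00622) and AT2G29500 (-4.25 ± 0.46, adjusted p = 0.0021), AT3G15460 (-3.20 ± 0.27, adjusted p = 0.000965) and ICU2 (-2.38 ± 0.42, adjusted p = 0.0126). AT3G62950 fell by 5.23 in WT and changed by -1.49 in tor (difference 3.74 ± 0.59, adjusted p = 0.00823), and AT4G27450 by -4.17 and -0.74 (3.43 ± 0.63, adjusted p = 0.0155). AKINBETA1 fell by 3.26 in WT and changed by -0.57 in tor (2.69 ± 0.48, adjusted p = 0.0131). In all, 782 had a smaller rise and 437 a smaller drop in tor, and 0 changed in tor by over 1 in the other direction, an account that uses the same WT arrays for the response and for the difference. Of the WT-responsive probe sets, 25.4% of those that rose and 18.4% of those that fell were called different, or 55.2% and 46.8% with the replicate number as a block. Rises in tor relative to WT made up 35.9% of the calls, and 49.1% after the arrays were centred on their medians. The centring took off a shift of -0.06, while the median difference over probe sets was 0.01. The count was 3043 with the block. Leaving out 1 array gave 477 (without WT_none array 2), 631 (WT_none array 3), 502 (WT_glucose array 2), 563 (WT_glucose array 3), 729 (tor_none array 1), 721 (tor_none array 2), 512 (tor_glucose array 2) and 483 (tor_glucose array 3).

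Of the 7 ribosome biogenesis genes, 5 had a lower log2 change in tor and 2 did not pass (6 when adjusted over the list alone), with a median difference of -1.68 ± 0.11 (SD over pairs; camera, adjusted p = 4.41e-09, adjusted p = 0.0238 with an estimated correlation, alternatives 1.09e-10 to 0.0238). NRPA1 (-1.81 ± 0.28, adjusted p = 0.00693), AT3G05060 (-1.70 ± 0.26, adjusted p = 0.00738) and AT1G52930 (-1.68 ± 0.22, adjusted p = 0.00406) were among them. Of the 5 starvation genes 3 had a higher change in tor, a smaller drop, and 2 did not pass (5 when adjusted over the list alone), median 2.73 ± 0.58 (camera, adjusted p = 3.34e-06), and of the 14 autophagy genes 4 had a higher change and 10 did not pass (5 when adjusted over the list alone), median 0.64 ± 0.18 (camera, adjusted p = 1.43e-06), ATG8C by 1.27 ± 0.23 (adjusted p = 0.0128). Both list calls were lost with an estimated correlation, at adjusted p = 0.101 with an estimated correlation for starvation (alternatives 1.85e-07 to 0.101) and 0.119 for autophagy (1.52e-07 to 0.119). Of the starvation and autophagy genes called, AKINBETA1 and ATG8C alone kept the call when any 1 array was left out. None of the 9 ribosomal protein genes passed (0 also when adjusted over the list alone), median -0.56 ± 0.07, where camera gave an adjusted p of 0.000767, adjusted p = 0.249 with an estimated correlation (1.44e-05 to 0.249), and fry 0.076. SDH1-1 differed by -0.90 ± 0.16 (adjusted p = 0.0137), the single call among 3 glycolysis and TCA cycle genes, also when adjusted over the list alone. It lay at 9.76 in untreated tor against 9.04 in untreated WT. With glucose it lay at 9.98 in tor and 10.16 in WT, a difference that did not pass (-0.18 ± 0.11, adjusted p = 0.228). Besides ICU2, PRL differed by -2.21 ± 0.67 without passing (adjusted p = 0.0852), and both S-phase genes passed when adjusted over the list alone. Beta-oxidation had 0 calls of 3 (2 when adjusted over the list alone) and root hair markers 0 of 2 (1 when adjusted over the list alone); UGT74B1, 1 of 2 glucosinolate genes, passed (1 also when adjusted over the list alone; -0.95 ± 0.23, adjusted p = 0.0416) and lost the call without any 1 of 10 arrays, with the highest adjusted p of 0.111 without WT_none array 2. No member passed, over all probe sets or when adjusted over the list alone, in the mitotic, TOR pathway, photosynthesis, flavonoid, cell wall, root meristem, handling stress, clock and reference lists. With the replicate number as a block, 6 of 7 biogenesis, 5 of 5 starvation, 5 of 14 autophagy and 3 of 9 ribosomal protein genes (AT3G09630, adjusted p = 0.0447) were called different. So were both S-phase genes (PRL, adjusted p = 0.0164) and 2 of 3 genes of beta-oxidation (ICL, adjusted p = 0.0147).

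**Figure D4:**
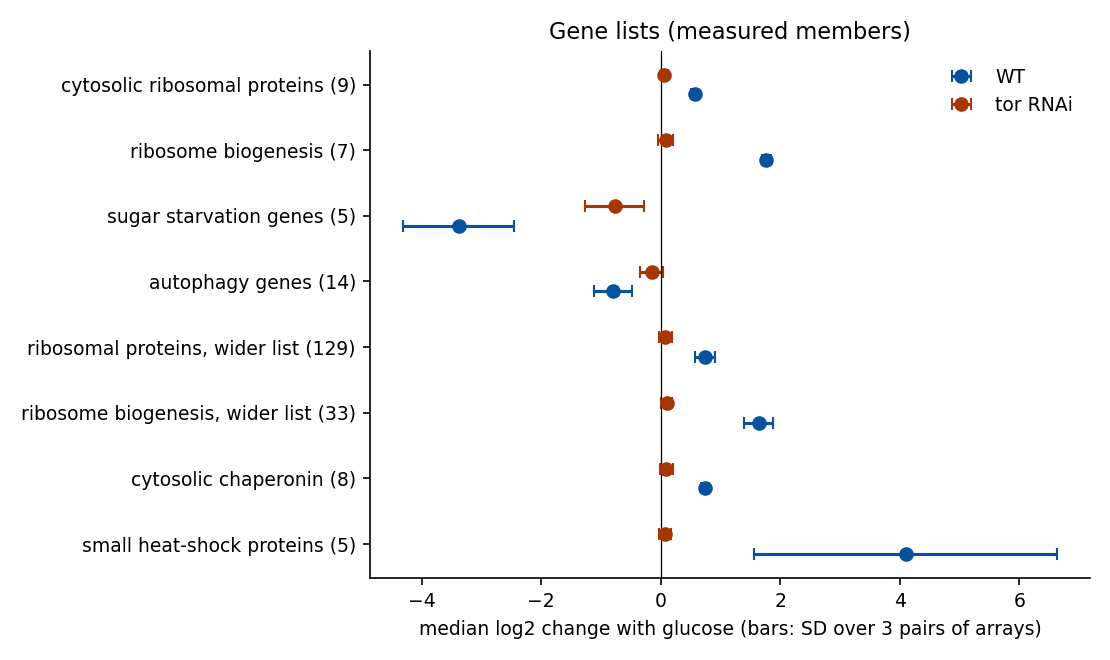
Median log2 change with glucose of the measured members of each tested list (number in brackets) in WT and tor, bars for the SD over the 3 same-number pairs, the last 4 lists chosen after the data were seen. Ribosome biogenesis is at 1.76 for glucose in WT and 0.08 in tor, sugar starvation at -3.38 and -0.77.

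Without glucose, tor and WT seedlings already differed at 6408 probe sets, 4438 higher and 1970 lower in tor. The array medians of tor lay 0.24 (log2) higher without and 0.18 higher with glucose. The median of the genotype differences over probe sets was smaller, 0.08 without and 0.08 with glucose. The genotype differences given here are not corrected for either. Median centring takes off the full shift of the array medians, more than the median difference. Rises made up 69.3% of the calls without glucose, 50.7% after a second quantile normalization and 33.0% after median centring. RAPTOR2 and RAPTOR1, which encode the binding partner of TOR, were higher in tor by 1.45 ± 0.23 (adjusted p = 0.00134) and 1.38 ± 0.28 (adjusted p = 0.0052), 2 of 2 TOR pathway genes measured, also when adjusted over the list alone. AT3G15460 was higher by 1.49 ± 0.19 (adjusted p = 0.000347), UGT74B1 by 1.56 ± 0.16 (adjusted p = 0.000109) and SDH1-1 by 0.72 ± 0.11 (adjusted p = 0.00128). Isocitrate lyase was lower (ICL, -1.07 ± 0.24, adjusted p = 0.00711) and the peroxisomal AIM1 higher (1.04 ± 0.25, adjusted p = 0.0115). The root-hair expansin EXPA7 was lower by -2.01 ± 0.26 (adjusted p = 0.000394) and tny, an AP2-type transcription factor gene, by -3.57 ± 0.22 (adjusted p = 3.89e-06). EXPA7 lay at 4.82 without and 4.83 with glucose in tor, below 5. Its differences are lower limits. Among named genes the largest differences were of genes at the level of dark probe sets in WT, led by AT5G59845 at 3.83 in WT and 12.18 in tor (adjusted p = 5.66e-09). Signal of the 3' over the 5' end of the control transcripts also differed between the groups: for GAPDH it was 0.79 ± 0.20 (log2, SD) in WT and 1.24 ± 0.30 in tor without glucose, 0.63 ± 0.07 and 0.96 ± 0.11 with glucose, and for ubiquitin 1.73 ± 0.07 and 1.44 ± 0.15, then 1.73 ± 0.11 and 1.41 ± 0.04. For actin it was 1.75 ± 0.34 in WT and 1.92 ± 0.44 in tor without glucose, 2.04 ± 0.10 and 1.80 ± 0.12 with glucose, so the 3 controls did not shift one way.

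Of 14 autophagy genes 7 were higher in tor without glucose and 7 did not pass (9 when adjusted over the list alone), median 0.58 ± 0.13, among them APG8A (ATG8A) by 0.94 ± 0.19 (adjusted p = 0.00529) and AT3G59950 (ATG4B) by 0.82 ± 0.13 (adjusted p = 0.0013). The camera test gave 0.0179 for this list, a call lost at adjusted p = 0.462 with an estimated correlation and at 0.0824 without WT_none array 1 (alternatives 0.00228 to 0.462). Of 9 ribosomal protein genes 3 were lower and 6 did not pass (4 lower when adjusted over the list alone), median -0.54 ± 0.28 (camera, adjusted p = 0.00141, adjusted p = 0.462 with an estimated correlation, 0.0909 after a second quantile normalization, alternatives 1.93e-05 to 0.462). Of 5 starvation genes 1 was lower (1 also when adjusted over the list alone), AKINBETA1 by -1.14 ± 0.34 (adjusted p = 0.0292). That call was lost without WT_none array 2 (0.0809), WT_none array 3 (0.0806), tor_none array 1 (0.0795) or tor_none array 2 (0.0634). The list did not pass (median -0.89 ± 0.50, camera, adjusted p = 0.0536), except without WT_none array 1 (0.0382), WT_glucose array 1 (0.0393), tor_none array 2 (0.0251), tor_none array 3 (0.0132) or tor_glucose array 3 (0.0462; alternatives 0.0132 to 0.462). Of 7 biogenesis genes AT3G15460 alone was higher (1 also when adjusted over the list alone), and the median of 0.09 ± 0.38 did not pass (camera, adjusted p = 0.468) and turned to -0.10 and -0.15 under quantile normalization and median centring. Of the small lists, beta-oxidation had 1 higher and 1 lower of 3, glycolysis and TCA cycle 1 higher of 3, glucosinolates 1 higher of 2, photosynthesis 1 higher of 2, handling stress 1 higher of 1 and root hair markers 1 lower of 2, with the same counts when adjusted over the list alone. The calls of LHCB4.2 (0.70 ± 0.22, photosynthesis) and STZ (1.81 ± 0.58, handling stress) were lost without WT_none array 1 (0.115 and 0.0793), WT_none array 3 (0.113 and 0.129), tor_none array 2 (0.109 and 0.112) or tor_none array 3 (0.0732 and 0.131), that of LHCB4.2 also without tor_none array 1 (0.0529), and that of STZ without WT_glucose array 3 (0.0521) or tor_glucose array 2 (0.0501). S-phase genes had 0 of 2 (1 lower when adjusted over the list alone), reference genes 0 of 2 (1 higher when adjusted over the list alone) and mitotic, flavonoid, cell wall, root meristem and clock genes 0 of 3, 1, 1, 1 and 1 (0 when adjusted over the list alone). With the replicate number as a block, 9 of 14 autophagy and 2 of 7 biogenesis genes were higher and 5 of 9 ribosomal protein genes lower. The block also called 2 of 3 mitotic genes (AUR3, adjusted p = 0.00885) and 1 of 2 S-phase genes (ICU2, adjusted p = 0.0471) lower, 1 more glycolysis and TCA cycle gene lower, and DFR of the flavonoid list (adjusted p = 0.00396) and the reference gene AT4G34270 (adjusted p = 0.0467) higher.

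With glucose the genotypes stood further apart, at 9418 probe sets, 5776 higher and 3642 lower in tor. Rises made up 61.3% of the calls, 49.5% after a second quantile normalization and 41.9% after median centring. AT2G29500 was lower in tor by -4.66 ± 0.32 (adjusted p = 8.89e-06) and AT1G53540 by -4.27 ± 0.48 (adjusted p = 0.000119), both lower limits, with tor below 5. Both S-phase genes were lower, also when adjusted over the list alone: ICU2 by -3.17 ± 0.30 (adjusted p = 4.34e-05, a lower limit for the same reason) and PRL by -2.82 ± 0.47 (adjusted p = 0.00105). All 9 ribosomal protein genes were lower, also when adjusted over the list alone, median -1.07 ± 0.28, with AT3G53890 (RPS21B) at -1.68 ± 0.29 (adjusted p = 0.00119). Of 7 biogenesis genes 6 were lower and 1 did not pass (7 when adjusted over the list alone), median -1.58 ± 0.13, with AT1G52930 at -1.62 ± 0.16 (adjusted p = 5.1e-05). All 5 starvation genes were higher, also when adjusted over the list alone, median 2.35 ± 1.19, with MCCA at 3.36 ± 0.77 (adjusted p = 0.00567) and AT3G15450 (SEN5) at 2.35 ± 0.37 (adjusted p = 0.000731). Of 14 autophagy genes 12 were higher and 2 did not pass (13 when adjusted over the list alone), median 1.14 ± 0.21, with APG8A at 2.00 ± 0.19 (adjusted p = 5.17e-05). The camera tests gave 2.35e-06 for ribosomal proteins and for autophagy, 4.14e-06 for biogenesis and 0.0104 for starvation. All 4 calls were lost with an estimated correlation, at 0.147 for ribosomal proteins (alternatives 5.44e-07 to 0.147) and autophagy (8.94e-08 to 0.147), 0.0872 for biogenesis (1.41e-06 to 0.0872) and 0.246 for starvation (4e-04 to 0.246).

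RAPTOR1 stayed higher in tor with glucose (1.49 ± 0.28, adjusted p = 0.00215), as did RAPTOR2 (0.92 ± 0.23, adjusted p = 0.00946) and AIM1 (1.25 ± 0.25, adjusted p = 0.00304). The zinc finger gene STZ, of the handling stress list, was higher by 2.94 ± 0.58 (adjusted p = 0.00248). The expansin genes EXPA8 and EXPA7 were lower by -2.76 ± 0.74 (adjusted p = 0.0126) and -2.20 ± 0.26 (adjusted p = 0.000154). Over the small lists, 2 of 2 TOR pathway genes, 2 of 3 beta-oxidation genes, 1 of 2 glucosinolate, 1 of 2 photosynthesis, 1 of 1 root meristem, 1 of 1 handling stress and 1 of 2 reference genes were higher, and 1 of 3 glycolysis and TCA cycle, 1 of 1 cell wall and 2 of 2 root hair genes were lower, with the same counts when adjusted over the list alone. The lower glycolysis gene was TPI (-0.52 ± 0.13, adjusted p = 0.00766). The root meristem gene, BBM, lay below 5 in each group (4.23 in WT and 4.70 in tor with glucose), where a change cannot be sized. The higher reference gene, AT4G34270 (0.34 ± 0.09, adjusted p = 0.0123), lost its call after a second quantile normalization (0.121) and after median centring (0.230). None of 3 mitotic, 1 flavonoid and 1 clock gene passed, or passed when adjusted over the list alone. Under the block on the replicate number all 3 mitotic genes were lower (AUR3, adjusted p = 0.00919) and the clock gene GI higher (adjusted p = 0.0308), and 13 of 14 autophagy and 7 of 7 biogenesis genes were called.

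On principal components of the 12 arrays the genotypes and, within WT, the treatments separated. The first component held 54.4% and the second 23.8% of the variance. The tor arrays numbered 1 lay at 18.3 and 21.9 on the first component, the other tor arrays between 60.5 and 73.1, and WT_none array 1 lay at -41.2 on the second, the other untreated WT arrays at -65.7 and -68.7. On the second component each tor array with glucose lay above the untreated one of its number (24.9 and 34.8, -2.33 and 15.9, -7.12 and 13.2). Correlations between arrays of 1 group ran from 0.966 to 0.991, those between arrays of different groups from 0.898 to 0.996.

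**Figure D5:**
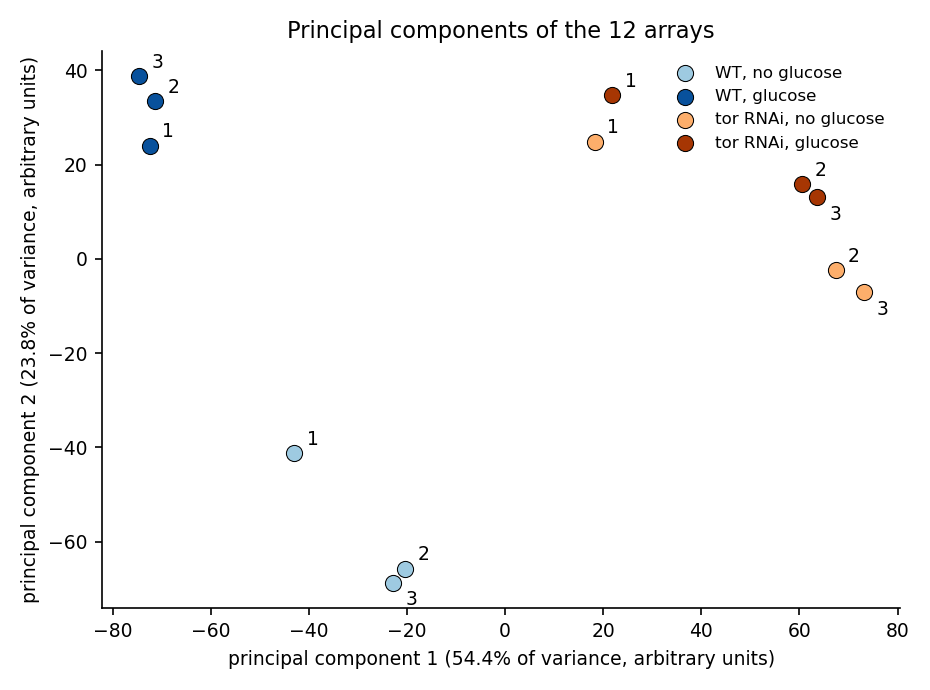
First and second principal component of the 12 arrays (54.4% and 23.8% of the variance), each point an array with its replicate number. The tor arrays numbered 1 lie at 18.3 and 21.9 on the first component, apart from the other tor arrays.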

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

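The tests of spread, swaps, positions, strain background and linkage were chosen only after the results were seen, with the bounds for positions, arrays numbered 1, strain background and linkage revised once their values were known. The test of the difference, the other splits of the arrays and leaving out single arrays were planned.

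The glucose response was tested for a difference between the genotypes, and 1220 probe sets passed. The median difference (tor minus WT) of ribosome biogenesis genes was -1.68 and that of its wider list -1.44, of cytosolic ribosomal proteins -0.56 and of their wider list -0.64, of cytosolic chaperonin genes -0.67 and of small heat-shock protein genes -3.82, a list written after 2 of its members were seen among the largest rises. Sugar starvation genes differed by 2.73 and autophagy genes by 0.64. Of the 38 single genes listed here, 20 kept the call when any 1 array was left out. Negative differences, a smaller rise in tor, were kept by AT1G53540 (-4.60), AT2G29500 (-4.25), AT3G15460 (-3.20), AT4G04940 (-2.81), ICU2 (-2.38), AT2G32220 (-2.20), AT3G10530 (-2.19), AT3G18600 (-2.08), NRPA1 (-1.81), AT3G05060 (-1.70), AT1G52930 (-1.68), AT3G02530 (-1.05), SDH1-1 (-0.90), AT3G18190 (-0.76) and AT5G20890 (-0.75). Positive differences, a smaller drop in tor, were kept by AT3G62950 (3.74), AT4G27450 (3.43), AT5G66650 (3.26), AKINBETA1 (2.69) and ATG8C (1.27).

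The other 18 genes lost the call without 1 or more arrays, listed with the highest adjusted p that leaving out 1 array gave. Without WT_none array 2 it was 0.0846 for AT1G19540 (3.27), 0.114 for AT1G22890 (3.27), 0.0548 for AT1G06000 (-3.55), 0.109 for AT5G54970 (-2.91), 0.0608 for AT1G55210 (-2.65) and 0.0778 for GH9C2 (-2.64). It was 0.0518 for AT3G15450 (2.73), 0.126 for ATG8E (1.98), 0.0510 for ATG8F (1.91), 0.113 for APG8H (0.81), 0.111 for UGT74B1 (-0.95), 0.0980 for AT1G23410 (-2.09), 0.0530 for AT3G57490 (-1.96) and 0.121 for AT3G03960 (-0.97). For MCCA (4.50) it was 0.103 without WT_glucose array 3, for PPDK (4.09) 0.0807 without tor_glucose array 2, and for AT4G25580 (3.72) and AT5G59240 (-1.80) 0.0523 and 0.0727 without tor_glucose array 3. Over all arrays, WT_none array 2 ended 17 of the calls, tor_glucose arrays 2 and 3 ended 16 each, WT_glucose arrays 3 and 2 ended 14 and 12, and WT_none array 3 ended 12. The tor_none arrays 2, 1 and 3 ended 10, 8 and 4, and array 1 of WT_glucose, tor_glucose and WT_none ended 4, 2 and 1.

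Other splits of the same arrays were counted for each comparison of groups. With 10 splits, each comparison is too small for a share under 0.05. Each other split also mixes arrays of both groups on each side, so a true difference widens its spread and lowers its calls. No conclusion is drawn from these counts. Of the 10 splits of the 6 WT arrays, 1 (the real one) called as many as 5454 probe sets, and the highest other called 1. For glucose in tor the real split called 0 and so did the others, so 10 of 10 were as large, which a real count of 0 fixes in advance. For the difference, on the 6 same-number differences, the real split called 4555 and the highest other 0, and for tor against WT the real splits called 6408 without and 9418 with glucose and the highest others 0, 1 of 10 as large in each. The other 3 splits that part all 3 same-number pairs called 0 in each comparison.

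No probe set passed for glucose in tor, although WT called 5454 at the same number of arrays, in a fit that gives a probe set the same standard error for both responses. A larger spread between tor arrays is argued against only for the same-number differences, whose median SD was 0.153 in tor and 0.206 in WT, a ratio of 0.744. The fit does not use this pairing but the spread within groups, which was not smaller in tor. Without and with glucose the median SDs within groups were 0.184 and 0.187 in tor and 0.183 and 0.155 in WT. The pairing matters for the count in tor: the tor arrays alone with the replicate number as a block gave 20 calls, the block within genotype 0. A swapped tor pair is argued against because in each of the 3 pairs the genes that rise in WT changed more than those that fall, by at least 0.12 (SD over pairs 0.11). An untreated tor state already at the WT glucose level is argued against for the responsive genes as a whole, since untreated tor lay 18.1% (SD 7.80) of the way to glucose-treated WT for rising genes and 23.1% (SD 19.7, from 0.315% to 34.6%) for falling ones. These values rest on medians and do not cover each gene. UGT74B1 lay at 9.50 in untreated tor, against 7.94 and 9.16 in WT without and with glucose. AT1G52930 lay at 8.77, against 8.71 and 10.52. A weaker response because of the silencing of TOR may also apply and was not tested, since TOR and the inducer in WT were not checked here.

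WT_none array 1 lay 30.1% of the way from untreated to glucose-treated WT on an axis drawn from numbers 2 and 3, where WT_none arrays 2 and 3 lay at 1.08% and -1.08%. A swap with WT_glucose array 1 is argued against, because that array lay at 88.1%. Over all probe sets, deviations from the group means correlated positively in each pair of arrays numbered 1 (0.199 to 0.863). Along this axis a shift shared by the arrays numbered 1 stays open. The tor_none array 1 was shifted the same way by 30.0%, against a distance of 3.63% between tor_none arrays 2 and 3. The tor_glucose array 1 lay at 43.9%, where tor_glucose arrays 2 and 3 lay at 26.2% and 26.0%. But WT_glucose array 1 went the other way, from 97.7% and 105% for arrays 2 and 3. Without WT_none array 1 the number of probe sets called different rose to 1828. An axis drawn from numbers 2 and 3 itself pulls the WT arrays numbered 1 inward, and no biological explanation was tested, since the design gives none.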

How the results depend on the processing

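Chosen after the data were seen were the block within genotype, the block in fits of only the arrays compared and leaving out the 4 arrays numbered 1. For glucose in WT and for tor against WT without and with glucose, each setting chosen in advance gave a count within 1.5 times the reported one (leaving out 1 array 3699 to 5949, 4273 to 6856 and 7154 to 9802). The block within genotype gave 8903 for WT. Glucose in tor had 0 calls under each setting chosen in advance, 2 without the arrays numbered 1 and 20 with the tor arrays alone and the block. The difference of the responses moved from 1220 to 3043 with the block, 3472 with array weights, 4555 with the block within genotype, 2936 without the arrays numbered 1, and 477 (without WT_none array 2) to 1828 (without WT_none array 1) when 1 array was left out. The tor medians of the WT-responsive probe sets were 0.18 and -0.25 for changes of at least 1 in WT, and ran from 0.050 (without tor_glucose array 1) to 0.20 (without tor_none array 1) for rising and from -0.21 (without tor_none array 1) to -0.082 (without tor_none array 3) for falling probe sets. Of 20 tests of the 4 planned lists 17 passed, 17 with the block and 14 to 18 when 1 array was left out. Without the block, 2 passed with an estimated correlation and 12 with fry. The wider list of ribosomal proteins reversed in tor without tor_none array 3 (-0.08) and without tor_glucose array 1 (-0.11), and its median ran from -0.11 to 0.33 (without tor_none array 1). Leaving out 1 array also breaks its same-number pair, and the cause of these moves was not tested. Over the single genes and alternatives, 4734 of 5074 kept the side of the threshold (29 of them, not called either way, changed sign), 270 lost and 70 gained the call and 0 called ones reversed. Of 760 list tests 692 kept the side (12 of them changed sign, not called either way), 58 lost and 8 gained the call and 2 called ones reversed. The planned settings for TOR and for values on a linear scale were not run, since TOR has no named probe set here and the values are log2. Signal over background limits dim genes: 5252 probe sets lie below 5 on all 12 arrays, and no change in them can be sized.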

Other observations

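The tests in this part, the 4 wider or added lists, the fit of the tor arrays with a block and the genes named from it were all chosen after the data were seen.

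The wider ribosome lists include members of the planned ones. The small heat-shock protein list was prompted by 2 members seen among the largest rises, so its camera tests are no support and are not given. They were run, are among the 760 list tests counted above and enter the adjustment for the other added lists. Of 33 genes of the wider ribosome biogenesis list 29 rose and 4 did not pass (30 when adjusted over the list alone), median 1.64 ± 0.24 (SD over pairs), among them AT4G04940 by 3.14 ± 0.22 (adjusted p = 2.27e-05). Of 129 ribosomal protein genes 62 rose and 67 did not pass (74 rose and 1 fell when adjusted over the list alone), median 0.74 ± 0.17, with AT2G32220 at 2.50 ± 0.19 (adjusted p = 3.36e-05). Of 8 cytosolic chaperonin genes, which fold newly made proteins, 7 rose (8 when adjusted over the list alone), median 0.74 ± 0.06, and of 5 small heat-shock protein genes 4 rose (4 when adjusted over the list alone), with log2 changes from 0.87 to 4.48 over the list. With the replicate number as a block 30 biogenesis, 81 ribosomal protein and 8 chaperonin genes rose and 1 ribosomal protein gene fell. The camera tests of the first 3 lists gave 3.53e-22, 1.66e-14 and 7.66e-07, and each call was lost with an estimated correlation (0.0534, 0.234 and 0.0858, the highest over 19 alternatives, from 2.54e-26, 3.21e-19 and 2.1e-07).

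In tor none of these genes passed (0 also when adjusted over the list alone), and the medians were 0.10 ± 0.09 for biogenesis, 0.08 ± 0.10 for ribosomal proteins, 0.10 ± 0.10 for chaperonin and 0.08 ± 0.10 for small heat-shock proteins. The camera tests of the first 3 gave 0.000445, 0.00257 and 0.0247, with each call lost with an estimated correlation (0.397, 0.724 and 0.397). The lowest alternatives were 4.1e-05, 2.58e-20 and 0.00441, and fry, which asks another question than camera, gave 0.584, 0.797 and 0.584. The ribosomal protein median was 0.04 without tor_none array 2 (0.403), and -0.08 and -0.11 without tor_none array 3 (0.0117) or tor_glucose array 1 (0.000774). The chaperonin call was lost with a block (0.0559) and without tor_none array 2 (0.243) or 3 (0.139) or tor_glucose array 1 (0.125) or 3 (0.0574). The difference between the genotypes was called for 23 of 33 biogenesis genes (26 when adjusted over the list alone), 9 of 129 ribosomal protein genes (10), 4 of 8 chaperonin genes (8) and 2 of 5 small heat-shock protein genes (4), each with a lower change in tor. With the block these counts were 28, 36, 5 and 2. The camera tests of the first 3 gave 1.16e-25, 4.75e-13 and 4.15e-07, and 0.0369, 0.258 and 0.0743 with an estimated correlation, the highest over the alternatives (from 6.53e-31, 1.85e-20 and 6.7e-08).

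Between the genotypes without glucose, 34 of 129 ribosomal protein genes were lower and 2 higher in tor (34 and 2 when adjusted over the list alone), median -0.52 ± 0.31 (camera, adjusted p = 2.6e-13, 0.692 with an estimated correlation, alternatives 3.1e-23 to 0.692). AT4G39200 was lower by -1.24 ± 0.25 (adjusted p = 0.00506). Biogenesis had 2 higher and 1 lower of 33 (1 and 0 when adjusted over the list alone), chaperonin 0 of 8 and small heat-shock proteins 0 of 5 (0 and 0), with medians of 0.15, 0.15 and 0.33, the first 2 without passing (camera, 0.687 and 0.687). With the block 68 ribosomal protein genes were lower and 2 higher, and biogenesis had 6 higher and 1 lower, chaperonin 2 higher and small heat-shock proteins 1 higher. The first 2 medians turned to -0.09 and -0.09 after median centring, and that of biogenesis also lay below 0 after a second quantile normalization. With glucose 115 of 129 ribosomal protein genes were lower and 1 higher (116 and 1), 30 of 33 biogenesis genes (32), 6 of 8 chaperonin genes (6) and 3 of 5 small heat-shock protein genes (4) were lower, with medians of -1.14 ± 0.39, -1.28 ± 0.32, -0.69 ± 0.15 and -2.42 ± 1.28. The 1 higher ribosomal protein gene lies below 5 in each group mean, where a change cannot be sized. With the block 116, 32, 6 and 4 were lower. The camera tests of the first 3 gave 4.22e-27, 5.36e-17 and 0.00013, and with an estimated correlation 0.126, 0.104 and 0.126, the highest over the alternatives (from 2.27e-34, 4.43e-20 and 3.18e-05).

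With the tor arrays alone and the replicate number as a block, 20 probe sets passed for glucose in tor, 5 higher and 15 lower, and 7 carry 1 gene here. GAT1_2.1 changed by -2.75 ± 0.25 (adjusted p = 0.0252; -5.16 in WT), AT3G15440 by -1.48 ± 0.14 (adjusted p = 0.0252), AT3G20340 by -1.36 ± 0.13 (adjusted p = 0.0252) and AT1G68440 by -0.90 ± 0.10 (adjusted p = 0.0355). AT5G10130 changed by 1.03 ± 0.10 (adjusted p = 0.0255), AT1G05280 by 0.85 ± 0.09 (adjusted p = 0.0355) and AT3G13610 by 0.79 ± 0.09 (adjusted p = 0.0365). All 20 had the same sign in WT, 18 were called there, and 2 were called different between the genotypes. Under the other alternatives for this comparison at most 2 probe sets passed.

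A hypothesis was that starvation genes keep a larger share of their WT response in tor than ribosome biogenesis genes do. The tor change was 19.9% (SD 11.3) of the WT change for starvation and 5.30% (SD 7.15) for biogenesis, a difference of 14.6 percentage points. The starvation share was the larger in all 3 pairs (7.66% against 5.90%, 30.0% against -2.13%, 22.1% against 12.1%), but the difference was smaller than its SD over them, so the test left it open. Another was that untreated tor seedlings may be shifted towards the glucose-treated state. Across probe sets, the WT glucose change of one number and the untreated tor minus WT difference of another correlated at a mean r of 0.159 (0.0831 to 0.242 over 6 choices), too weak to decide either way.

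Some probe sets were dark (below 5) in all 6 arrays of a genotype and bright (above 9) in all 6 of the other. Dark in WT and bright in tor were 4: AT5G59845 (4.04 and 12.16), AT1G56710 (3.75 and 11.03), AT1G71470 (3.81 and 10.44) and AT1G33320 (3.99 and 10.35). Another strain background of the tor line stays open, since 0 probe sets dark in tor and bright in WT against 4 are too few to decide, and so does a linked stretch of the genome, since 0% of these genes had another within 5 genes but the median of random draws was 0% too. Neighbouring effects of the inserted construct, the inducer and the silencing may each contribute and were not tested.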
